A study of Homo sapiens with 9 samples.

How the data were processed

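Gene expression was measured on 9 Affymetrix arrays hybridised with labelled RNA from U251 cells, an established line from a human malignant glioma. The 3 groups had 3 cultures each and received a small interfering RNA (siRNA) against WT1, a non-targeting (scrambled) siRNA, or the transfection reagent Oligofectamine alone. Both siRNAs were used at 100 nM. Groups and replicate numbers were taken from the sample titles. The series design calls the arrays biological triplicates, and the growth protocol describes wells plated in triplicate for each condition. Without a term for the replicate number, p-values measure the spread between the cultures of a group, including what differs between numbers. With the number as a block, described below, they measure the spread left once differences shared by a number are removed. Whether the replicate numbers stand for different days is not given in the sources used here.

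Per the labels, the authors processed the arrays with RMA (robust multi-array average), so that the deposited values are log2 expression per probe set, corrected for background and normalised between arrays. The software, its version and the chip definition are not given in the sources used here. The deposited table had 22277 probe sets, 0 missing values and 0 arrays with identical values. The 62 control probe sets of the chip were left out of the tests, which left 22215. Gene symbols came from the deposited probe annotation, and 19052 probe sets were looked up again by gene ID, which changed 0 symbols. Of the probe sets, 19064 had 1 gene symbol, 1043 had several and 2108 had none. The sources used here name no genome build for the probes, so no coordinates are given. RNA quality was not given and was judged from the control probe sets at the 3' and 5' ends of control transcripts. For arrays, their number limits the precision.

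The log2 values were used as deposited. Linear models were fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3 to all 9 arrays at once, with 1 mean per group, and each probe set was tested two-sided in each comparison. P-values were adjusted after Benjamini and Hochberg over all tested probe sets in each comparison, and an adjusted p under 0.05 was counted as a change. A probe set changed against both controls when it passed in both comparisons with the same sign. Figures were drawn with matplotlib 3.10.9.

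The design fixed before the data were examined had no term for the replicate number and listed the number as a block among its alternatives. Whether arrays with the same number go together was checked on the deviations of each array from its group mean over all probe sets. The 9 pairs with the same number in different groups had correlations of 0.647 to 0.849, and pairs with other numbers had correlations of −0.611 to −0.031. For 9 of the 9 arrays the closest array of another group carried the same number. The sum of squares over all probe sets was 71.4% between numbers and 15.6% between groups. Each result is therefore given without the block and, where the call or count differs, also with the replicate number as a fixed block (the blocked fit). The blocked fit was chosen to carry the description of genes after its counts had been seen.

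Gene lists were written before the data were examined: 31 lists of pathways, complexes and markers of cell types, among them 1 of reported WT1 targets. Each gene was represented by the probe set with the highest mean over all arrays, which gave 11963 genes. Shifts were tested with camera in limma with a preset correlation of 0.01, adjusted over the lists in each comparison, and repeated with an estimated correlation and with fry. With an estimated correlation, 0 lists passed in any comparison in either fit. Members were counted at an adjusted p over all probe sets and at one adjusted over the list alone. ADGRE5 belongs to 2 of the lists (reported WT1 targets and adhesion receptors) and was linked to WT1 in work on this series, so it is not independent evidence there.

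Genes were named by a rule fixed before the data were examined. WT1 and ADGRE5 were always named. Of the probe sets changed against both controls, ranked by the smaller absolute change, up to 12 lower and 12 higher genes were named, if every array with the WT1 siRNA lay beyond every array of both control groups. For each single comparison the 5 genes with the greatest rise and the 5 with the greatest fall among those called were named. Where fewer than 10 probe sets passed, those with the smallest p, up to 10, were named as not passing. For each list described, up to 4 members with the smallest p were named.

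The procedure was tested on simulated data with the spread and the replicate structure of these arrays, with 100 probe sets changed by 0.5 and 100 by 1 on the log2 scale. Without the block, 7% of the smaller changes were recovered against scrambled siRNA and 15% against reagent, and 67% of the larger in either comparison, with 0 false calls. With the block these shares were 97% and 96% of the smaller and 100% of the larger, with 12 false calls in each of these comparisons. In the simulated comparison without changes either fit made 0 calls. A list with a simulated shift was recovered in either fit, and 0 other lists were called. Apart from the replicate structure, genes varied independently in these data. They therefore do not show how often camera calls a list whose genes vary together.

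Alternatives were the replicate block, leaving out each array, quantile normalisation, centring on array medians, a filter on the dimmest probe sets, fitting the groups of a comparison alone, an intensity trend with a robust prior, array weights, 1 probe set per gene, an added 1.5-fold limit and an adjusted p under 0.1. The same alternatives in the blocked fit, and leaving out each replicate number, were chosen after seeing the data. Because comparisons share arrays, overlaps of calls were set beside 100 simulated data sets without any group difference and beside independent lists of the same length. From each simulated data set, as many probe sets as were called in the data were taken by smallest p, whether or not they passed. Probe sets varied independently in these simulations.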

Results

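Transcript levels were measured on 9 arrays in U251 cells, an established human glioma line, in 3 groups of 3 cultures. One group received an siRNA against WT1, a zinc finger transcription factor first described in Wilms tumour of the kidney. The other groups received a scrambled siRNA or the transfection reagent alone. The 22215 probe sets tested covered 11963 genes. Array medians lay between 6.45 and 6.53 on the log2 scale. For arrays, their number limits the precision. The groups carried the same replicate numbers, and the numbers accounted for more of the spread than the groups (71.4% of the sum of squares against 15.6%). Values are therefore given from the fit without the replicate number and, where the call differs, from the blocked fit, in which each comparison is made within a replicate number. Changes are on the log2 scale, with the standard error (SE) of the fit named and n = 3 per group, and p-values are from limma.

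**Figure D1:**
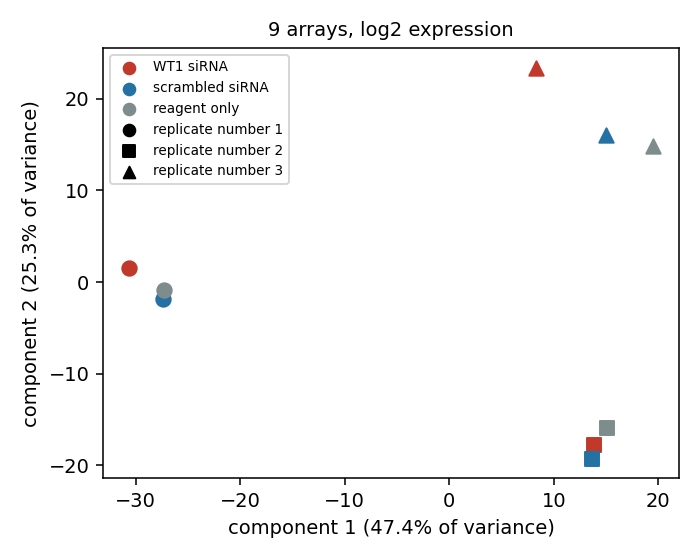
Each point is an array placed by its scores on the first (x axis, 47.4% of the variance) and second (y axis, 25.3%) principal component of the log2 values, coloured by group and marked by replicate number. Arrays lie together by replicate number, with the 3 groups side by side within each number.

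The first comparison asked how far the siRNA lowered its own target. WT1, at the brighter of its probe sets, had a mean log2 level of 4.89 (SD 0.172, n = 3) with the WT1 siRNA, 5.63 (SD 0.243) with the scrambled siRNA and 6.18 (SD 0.36) with reagent alone. The level with the WT1 siRNA was 60.0% of that with the scrambled siRNA, a log2 difference of −0.74 that was lower in 3 of 3 replicate numbers (−0.82, −0.80 and −0.59). Against reagent it was 41.0%, a difference of −1.29 that was also lower in 3 of 3 numbers (−1.29, −1.50 and −1.07). With its siRNA WT1 was brighter than 18.4% to 26.5% of the probe sets on the same array, near background. Background can hide part of a fall, so less may have remained than the estimates of 60.0% and 41.0%, but this was not measured. WT1 was itself lower with the scrambled siRNA than with reagent, at 68.4% (−0.55). The dimmer WT1 probe set lay at 4.94, 5.11 and 5.08 in these groups. With the WT1 siRNA it stood at 88.6% of the scrambled and 90.2% of the reagent level. It passed in no comparison (blocked adjusted p = 0.42 against scrambled siRNA and 0.516 against reagent). ADGRE5, the adhesion receptor CD97 that work on this series linked to WT1, had a mean of 7.91 (SD 0.221) with the WT1 siRNA, 8.64 (SD 0.0794) with the scrambled siRNA and 8.57 (SD 0.0947) with reagent. It stood at 60.0% of the scrambled level (−0.74) and 63.2% of the reagent level (−0.66), lower in 3 of 3 numbers in both comparisons.

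Without the block WT1 passed in neither comparison (SE 0.194, adjusted p = 0.672 against scrambled siRNA and 0.394 against reagent). ADGRE5 did not pass either (SE 0.116, adjusted p = 0.203 and 0.394). In the blocked fit WT1 fell against scrambled siRNA (SE 0.0811, adjusted p = 0.00336) and against reagent (adjusted p = 0.000619), and ADGRE5 fell in the same comparisons (SE 0.109, adjusted p = 0.00903 and 0.0245). The difference in WT1 between scrambled siRNA and reagent passed in the blocked fit too (adjusted p = 0.0164). Without the 3 arrays of replicate number 2 the WT1 changes of −0.70 and −1.18 no longer passed (adjusted p = 0.0795 and 0.0762). The ADGRE5 call was less stable: under 19 alternatives to the blocked fit it passed in 15 against scrambled siRNA (adjusted p up to 0.202) and in 12 against reagent (up to 0.359).

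**Figure D2:**
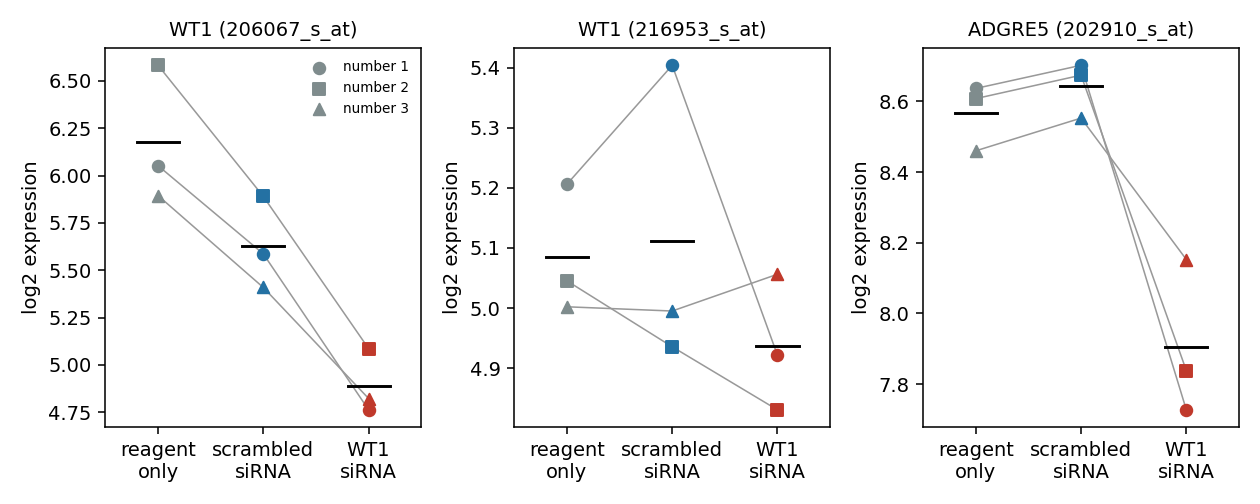
Log2 level (y axis) of both WT1 probe sets and of ADGRE5 in each of the 9 arrays by group (x axis), with lines joining arrays of the same replicate number and bars at the group means. The brighter WT1 probe set has means of 4.89, 5.63 and 6.18 with WT1 siRNA, scrambled siRNA and reagent, and ADGRE5 has 7.91, 8.64 and 8.57.

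The comparison of the WT1 siRNA with the scrambled siRNA asked which transcripts differ when both groups carry an siRNA. LAMC1, a laminin chain of basement membranes, rose 2.95-fold (log2 1.56, SE 0.0867, adjusted p = 0.000913), but its other probe set rose by less (0.39, blocked adjusted p = 0.016). INPP5A, which removes a phosphate from inositol trisphosphate and so ends calcium signals, fell 2.63-fold (−1.40, SE 0.129, adjusted p = 0.0256). PDGFD, a ligand of the PDGF receptor beta, fell 2.52-fold (−1.33, SE 0.127, adjusted p = 0.0256). TMF1, a Golgi protein, fell 1.62-fold (−0.70, SE 0.0693, adjusted p = 0.0262), while its other probe sets (−0.15 and 0.10) did not pass. These 4 probe sets, 1 higher and 3 lower, were the calls without the block. The next smallest p-values did not pass there: ANXA1 (0.57) and a probe set without a gene symbol (−1.50) had an adjusted p of 0.103 each, PPP2R1B (0.99) had 0.104, and TMEM9B (−0.68), RNF11 (−0.65) and another without a symbol (−0.65) had 0.126. All 6 of these passed in the blocked fit, with ANXA1, the phospholipid-binding annexin A1, at an adjusted p of 0.00345.

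The blocked fit called 726 probe sets of 560 genes against scrambled siRNA, 296 higher and 430 lower. Among probe sets with a gene symbol PRR16 fell most, 3.24-fold (−1.70, SE 0.15, adjusted p = 0.00122), followed by INPP5A, PDGFD, LRRC17 (−1.15, SE 0.116, adjusted p = 0.0024) and SORL1, a sorting receptor of endosomes (−1.09, SE 0.144, adjusted p = 0.00629), whose other probe set did not pass (−0.35). The greatest rises after LAMC1 were those of PPP2R1B, a scaffold subunit of protein phosphatase 2A (0.99, adjusted p = 0.000859; 2 of its 4 other probe sets passed), LOX, which crosslinks collagen (0.98, adjusted p = 0.0223), TXNIP, an inhibitor of thioredoxin (0.96, adjusted p = 0.0305; near background with scrambled siRNA at 5.15, while its brighter probe sets rose by 0.48 and 0.61), and MDFIC (0.92, adjusted p = 0.000932). PRR16 and LRRC17 were higher with the scrambled siRNA than with reagent, and LAMC1, PPP2R1B and MDFIC were lower. Of the 726, 121 also differed between scrambled siRNA and reagent with the opposite sign, 143 differed between WT1 siRNA and reagent with the same sign, and 464 passed in neither.

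Genes of the unfolded protein response, which answers misfolded protein in the endoplasmic reticulum, shifted up against scrambled siRNA, with a median of 0.21 and 25 of 28 genes above 0. The list passed camera without the block (adjusted p = 0.00116) and with it (adjusted p = 1.96e-05), and did not with an estimated correlation (blocked adjusted p = 0.975). With the block 4 of its genes rose and 1 fell, or 7 and 1 adjusted over the list alone, among them MANF (0.57), DDIT4 (0.54), PDIA3 (0.35) and EDEM1 (−0.34). Its call was lost without WT1 siRNA replicate 2 (blocked adjusted p = 0.245) and without replicate number 2 (0.339), and in the fit without the block when scrambled replicate 1 (0.351) or WT1 siRNA replicate 2 (0.525) or 3 (0.281) was left out. Oxidative phosphorylation genes shifted down (median −0.09, 34 of 35 below 0; camera adjusted p = 1.52e-06 without the block, 2.97e-05 with it, and a blocked adjusted p of 0.975 with an estimated correlation). Only NDUFA1 (−0.84) and NDUFB5 (−0.43) fell, over all genes and adjusted over the list alone (2 each). Hypoxia and glycolysis genes shifted up (median 0.07, 27 of 34 above 0; adjusted p = 0.00403 without the block and 0.000513 with it, and a blocked adjusted p of 0.334 with an estimated correlation). Of these, 4 genes rose and 0 fell, or 9 and 0 adjusted over the list alone, led by BNIP3L (0.40), DDIT4, PDK1 (0.34) and BNIP3 (0.42). The call without the block was lost without scrambled replicate 1 (0.168) or 2 (0.0717) or WT1 siRNA replicate 3 (0.33). Ribosomal protein genes passed only without the block (adjusted p = 0.0463, against 0.215 with it and 0.932 with an estimated correlation), with 0 genes called. That call was lost in 7 of the 9 fits that left out an array (up to 0.528), all but those without scrambled replicate 2 or WT1 siRNA replicate 3.

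Reported WT1 targets did not shift as a list (median 0.02; blocked camera adjusted p = 0.576). Among 47 genes 2 rose and 2 fell, or 4 and 3 adjusted over the list alone: ADGRE5 (−0.74, not independent evidence here), TGFB2 (−0.45), IGF1R (0.42) and LEF1 (0.35). Of the 25 adhesion G protein-coupled receptors and CD97 ligands, 3 fell and 0 rose, or 4 and 0 adjusted over the list alone, with ADGRG1 (−0.57) and ADGRG2 (−0.37) beside ADGRE5, and the list did not pass camera (blocked adjusted p = 0.327). Extracellular matrix and mesenchymal genes moved in both directions, 4 up and 2 down (7 and 6 adjusted over the list alone), without a shift of the list (blocked camera adjusted p = 0.67). LAMC1, LAMA4, another laminin chain (0.79), LOX (0.93 at the probe set used for the list) and COL1A2 (0.56) had the smallest p-values, and all rose. Of the proneural glioma and neural progenitor genes SOX2 (0.75) and DPYSL3 (0.59) rose and NOTCH2 (−0.30) and JAG1 (−0.40) fell (2 and 2, or 3 and 3 adjusted over the list alone; list adjusted p = 0.576). The astrocyte markers SLC1A3, a glutamate transporter (−0.70), and CLU (−0.48) fell, the only 2 calls among 15 genes over all genes or adjusted over the list alone. The list's median (0.04), mean (0.01) and camera (blocked adjusted p = 0.962) pointed up and fry pointed down. Of the 40 interferon-stimulated genes limma called 0 in any comparison in either fit, over all genes or adjusted over the list alone, and camera did not call the list (blocked adjusted p = 0.576 against scrambled siRNA).

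At an unadjusted p under 0.05 limma gave 825 probe sets without the block and 3640 with it. The blocked count was 224 without scrambled replicate 1, 208 without WT1 siRNA replicate 2, 88 without scrambled replicate 2, 395 without reagent replicate 2 and 292 without scrambled replicate 3, and 383, 2 and 374 without replicate numbers 1, 2 and 3.

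The comparison of the WT1 siRNA with reagent alone, the second control, asked the same with both the siRNA and its target in play. Without the block limma called 0 probe sets (616 at an unadjusted p under 0.05). The smallest p-values were those of TMF1 (−0.61, SE 0.0693, adjusted p = 0.304) and INPP5A (−1.01, SE 0.129, adjusted p = 0.387). PDGFD (−0.93), a probe set without a gene symbol (−0.60), WT1, PAFAH2 (−0.43), KCTD12 (−0.68), PAFAH1B1 (−0.52), RNF11 (−0.54) and NDUFA1 (−0.82) followed with an adjusted p of 0.394 each. In the blocked fit these 10 passed, WT1 (−1.29) with the greatest fall. It was followed by CILK1, a kinase of the primary cilium (−1.25, SE 0.167, adjusted p = 0.0115), INPP5A (adjusted p = 0.000619), NKAPD1 (−0.99, adjusted p = 0.0065) and TYMS, thymidylate synthase (−0.94, adjusted p = 0.00786). None of the other probe sets of TMF1, PAFAH2, KCTD12, PAFAH1B1 and TYMS passed (−0.44 to −0.10). The greatest rises were those of IGFBP5, which binds insulin-like growth factors (0.90, SE 0.102, adjusted p = 0.00786), SYT11 (0.88, adjusted p = 0.0181), TIMP3, an inhibitor of metalloproteinases (0.73, adjusted p = 0.0162), RORB (0.73, adjusted p = 0.00786) and FABP4 (0.69, adjusted p = 0.0154). IGFBP5, SYT11 and FABP4 also rose with the scrambled siRNA against reagent (0.66, 0.72 and 1.11, adjusted p up to 0.0348). None of them passed between the WT1 and scrambled siRNAs (0.24, 0.16 and −0.42, adjusted p = 0.278, 0.636 and 0.0536). The blocked fit called 277 probe sets of 227 genes, 91 higher and 186 lower (32.9% higher, or 21.1% after centring each array on its median). The share was 11.4% without WT1 siRNA replicate 2, 15.2% and 16.7% without reagent replicates 1 and 2, and 0% of 3 with the groups of the comparison fitted alone.

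Genes of G1/S and DNA replication shifted down against reagent, with a median of −0.13 and 27 of 32 below 0 (camera adjusted p = 1.69e-10 without the block, 2.35e-09 with it, and a blocked adjusted p of 0.418 with an estimated correlation). Of these, 3 fell and 0 rose, or 13 and 0 adjusted over the list alone: TYMS, MCM6 of the replicative helicase (−0.68) and UNG (−0.41) over all genes, and MCM3 (−0.30) over the list alone. Genes of G2/M and mitosis shifted down as a list (median −0.09, 33 of 37 below 0; blocked adjusted p = 8.37e-05, and 0.499 with an estimated correlation) with 0 called over all genes and 1, CCNA2 (−0.34), adjusted over the list alone. That call was lost without replicate number 3 (blocked adjusted p = 0.0612). Cholesterol synthesis genes shifted down in the blocked fit alone (median −0.15, 14 of 18 below 0; adjusted p = 0.000273, and 0.385 with an estimated correlation), where MSMO1 (−0.58) fell, with 5 genes lower adjusted over the list alone. Oxidative phosphorylation genes (median −0.03; blocked adjusted p = 0.0309, and 0.499 with an estimated correlation; 2 fell, over all genes or adjusted over the list alone) and ribosomal protein genes (median −0.03; blocked adjusted p = 0.0309, and 0.557 with an estimated correlation; 0 called) shifted down slightly. Both calls were lost without reagent replicate 2 (0.225 and 0.0703) or WT1 siRNA replicate 2 (0.2 and 0.0561), the first also without WT1 siRNA replicate 3 (0.0672) or reagent replicate 3 (0.0795), the second also without replicate 1 of the WT1 siRNA (0.183) or reagent (0.142). Without replicate numbers 2 and 3 the first had 0.274 and 0.106, and without numbers 1 and 2 the second had 0.274 and 0.0836.

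Extracellular matrix and mesenchymal genes shifted up against reagent, with a median of 0.15 and 33 of 41 above 0 (camera adjusted p = 2.27e-05 without the block, 4.05e-07 with it, and a blocked adjusted p of 0.385 with an estimated correlation). CCN2, connective tissue growth factor (0.57), and SPARC (0.34) rose over all genes, and 13 rose and 0 fell adjusted over the list alone, with LOXL2 (0.27) and CDH11 (0.32) among them. Hypoxia and glycolysis genes shifted up (median 0.12, 29 of 34 above 0; blocked adjusted p = 2.84e-05, and 0.201 with an estimated correlation). Of these BNIP3L (0.37) rose over all genes and 3 genes adjusted over the list alone. Genes of growth factor signalling and ERK feedback shifted up (median 0.09, 20 of 26 above 0; blocked adjusted p = 0.00488, and 0.385 with an estimated correlation). ETV4 (0.38) and DUSP5 (0.52) rose, the only 2 calls, or 3 adjusted over the list alone, and the list was lost without replicate number 2 (0.0608). The unfolded protein response (median 0.09, 24 of 28 above 0; adjusted p = 0.00832, and 0.614 with an estimated correlation) and the proteases of invasion (median 0.07, 21 of 34 above 0; adjusted p = 0.0309, and 0.499 with an estimated correlation) passed in the blocked fit alone. PDIA3 rose (0.49) and EDEM1 fell (−0.37) in the first, with 3 up and 1 down adjusted over the list alone, and in the second 0 genes were called over all genes and 6 rose adjusted over the list alone. Both calls were lost without WT1 siRNA replicate 2 (0.661 and 0.207) or reagent replicate 2 (0.271 and 0.0939), or replicate number 2 (0.701 and 0.224), the second also without reagent replicate 1 (0.0519). Without WT1 siRNA replicate 2 or replicate number 2 the unfolded protein response pointed down. Of 9 fits without the block that left out an array, the ribosomal call was lost in 4 (0.114 and 0.277 without WT1 siRNA replicates 1 and 2, 0.151 and 0.141 without reagent replicates 1 and 3) and that of growth factor signalling in 3 (0.572 without reagent replicate 1, 0.327 and 0.121 without WT1 siRNA replicates 2 and 3). Oxidative phosphorylation was lost without WT1 siRNA replicate 2 (0.327) or reagent replicate 3 (0.243), hypoxia without WT1 siRNA replicate 3 (0.0992) or reagent replicate 1 (0.0762), and G2/M without WT1 siRNA replicate 3 (0.119).

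Against reagent the adhesion receptors and CD97 ligands had ADGRE5 lower and ITGA5 higher (0.52), or 1 and 2 adjusted over the list alone. Of the astrocyte markers 0 were called (1 higher and 1 lower adjusted over the list alone, with SLC1A3 at −0.22 and CLU at −0.16). The WT1 targets had IGF1R higher and ADGRE5 lower, over all genes or adjusted over the list alone. The proneural list had SOX11 higher (0.57) and NOTCH2 lower (−0.37), or 2 and 1 adjusted over the list alone.

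At an unadjusted p under 0.05 the blocked fit gave 3359 probe sets. The blocked count of 277 became 465 without WT1 siRNA replicate 1, 44 without its replicate 2, 167 without its replicate 3, 92, 6 and 98 without reagent replicates 1, 2 and 3, 110 and 145 without scrambled replicates 2 and 3, 0 and 55 without replicate numbers 2 and 3, and 3 with the groups of the comparison fitted alone.

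Taking both controls, the question was which transcripts changed with the WT1 siRNA whichever control was used. Without the block limma called 0 probe sets (247 at an unadjusted p under 0.05 in both), and in the blocked fit it called 143 of 123 genes, 113 lower and 30 higher. Among the lower genes INPP5A fell by 1.40 on the log2 scale against scrambled siRNA and by 1.01 against reagent, PDGFD by 1.33 and 0.93, and NKAPD1 by 1.03 and 0.99. LSM14A, a component of RNA processing bodies, fell by 0.97 and 0.93, TYMS by 0.85 and 0.94, CILK1 by 0.85 and 1.25, and NDUFA1, a subunit of mitochondrial complex I, by 0.84 and 0.82. SORL1 (1.09 and 0.76), DBT, which acts in breakdown of branched-chain amino acids (0.78 and 0.69, near background with the WT1 siRNA at 5.16), and KCTD12 (0.69 and 0.68) also fell by these amounts, and with WT1 and ADGRE5 make up the 12 lower genes of the naming rule. Their blocked adjusted p-values reached 0.0288 at most against scrambled siRNA and 0.0418 against reagent.

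Among the higher genes TIMP3 rose by 0.82 and 0.73, RORB, a nuclear receptor, by 0.63 and 0.73, CITED2, a transcriptional coregulator, by 0.49 and 0.52, and the cell cycle kinase WEE1 by 0.63 and 0.42. SAT1, which acetylates polyamines (0.41 and 0.50), GABARAPL1, of autophagosomes (0.57 and 0.39), PINK1, a kinase of damaged mitochondria (0.42 and 0.43), and LIPA, the lysosomal acid lipase (0.37 and 0.40), rose too. IGF1R, the receptor of insulin-like growth factor 1 (0.42 and 0.38), BMAL1, of the circadian clock (0.33 and 0.43), and BSDC1 (0.30 and 0.32) complete the 11 higher genes, and their blocked adjusted p-values reached 0.0367 and 0.048 at most. Against reagent 7 of the 23 passed in fewer than 50% of the alternatives to the blocked fit: BSDC1 (5 of 19, and 5 of 19 against scrambled siRNA), LIPA (6 of 19), SORL1 (7 of 18), PINK1 (8 of 19), CITED2 and GABARAPL1 (8 of 18 each) and IGF1R (9 of 19). WEE1 passed in 9 of 18. Where 18 alternatives are counted, that of 1 probe set per gene took a brighter probe set of the gene and is left out. Of these 23 genes 15 had another probe set on the array. For 4 of them, LSM14A, TIMP3, CITED2 and PINK1, another probe set also passed against both controls, and for the remaining 11, WT1 among them, none did.

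Of the 143 probe sets, 71 had every WT1 siRNA array below all control arrays and 12 had every one above. Over all probe sets 272 lay below and 165 above in this way, 437 or 1.97% together, where chance gives 2.38% for such groups if the replicate numbers are ignored. Within the numbers, the 26 other choices of 1 array from each number separated 65 to 389 probe sets (median 108). Both comparisons use the same WT1 siRNA arrays, so their calls overlap without any effect in common. Independent lists of these lengths would share 4.81. In the 100 simulations without group differences, lists of these lengths were taken by smallest p, whether or not they passed. These lists shared a median of 79 with a range of 61 to 92. The range may be too narrow, since probe sets varied independently in the simulations. The correlation of changes over probe sets was 0.594 (0.501 simulated), and the covariance was 0.0115 (0.00308 simulated). The blocked count of 143 became 224 without WT1 siRNA replicate 1, 32 without its replicate 2, 73, 38 and 65 without scrambled replicates 1, 2 and 3, 67, 5 and 63 without reagent replicates 1, 2 and 3, 0 and 39 without replicate numbers 2 and 3, and 2 with the groups of each comparison fitted alone.

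**Figure D3:**
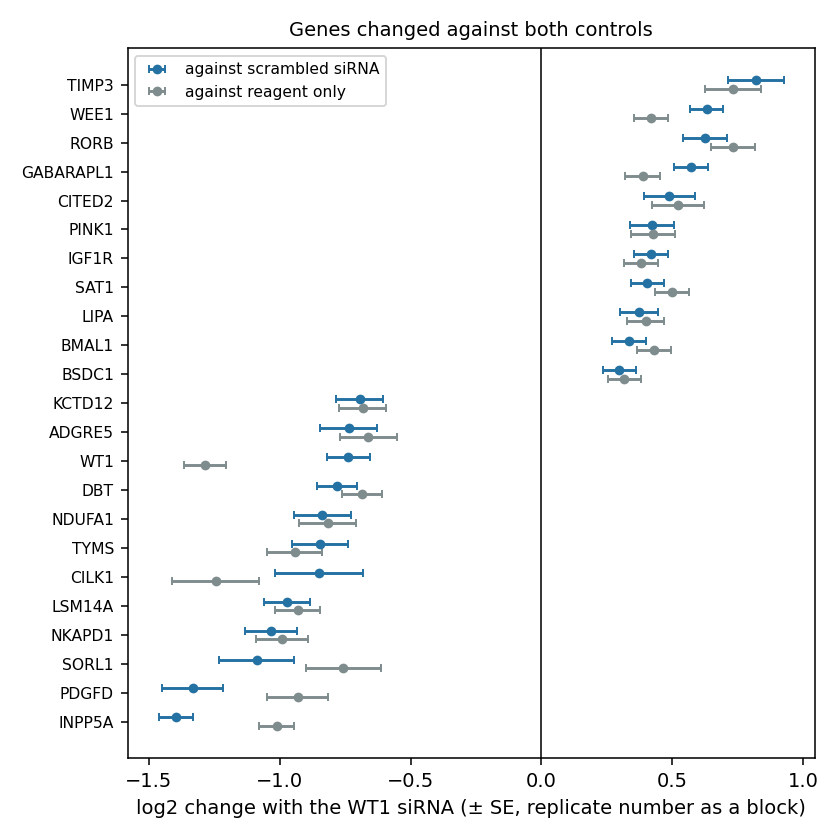
Log2 change with the WT1 siRNA (x axis) of the 23 genes named for both controls (y axis), against scrambled siRNA and against reagent, with bars of 1 SE from the blocked fit (n = 3 per group). The 12 lower genes range from INPP5A (−1.40) to KCTD12 (−0.69) against scrambled siRNA and from WT1 (−1.29) to ADGRE5 (−0.66) against reagent. The 11 higher genes range from TIMP3 (0.82 and 0.73) to BSDC1 (0.30 and 0.32).

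The comparison of scrambled siRNA with reagent asked what a non-targeting siRNA changes by itself. LAMC1 fell 2.45-fold (−1.29, SE 0.0867, adjusted p = 0.00436), the only call without the block, while its other probe set did not pass (−0.17, blocked adjusted p = 0.34). The next smallest p-values did not pass: COL5A1 (0.85, adjusted p = 0.427), then 3 probe sets of the splicing regulator MBNL1 (−0.97, −0.75 and −0.82), QKI (−0.72), GDPD5 (0.48), ANXA1 (−0.45), ZBTB20 (−0.92) and RPS27L (−0.61), each with an adjusted p of 0.429. The blocked fit called these too and 242 probe sets of 187 genes in all, 123 higher and 119 lower. The greatest falls after LAMC1 were those of NFIB, a transcription factor of glial development (−1.24, SE 0.0739, adjusted p = 0.000305), MDFIC (−1.06, adjusted p = 0.00093), MBNL1 (−0.97, adjusted p = 0.00325) and DST, a cytoskeletal linker (−0.93, adjusted p = 0.0164). None of the other probe sets of DST (7, from −0.49 to 0.02), QKI (5, from −0.27 to −0.05) or MDFIC (1, −0.58) passed. LRRC17 rose most, 2.68-fold (1.42, SE 0.116, adjusted p = 0.00176), followed by FABP4, a fatty acid carrier (1.11, adjusted p = 0.00274), PRR16 (1.07, adjusted p = 0.0138), SERPINI1, the protease inhibitor neuroserpin (0.97, adjusted p = 0.00495), and ARHGDIB (0.92, adjusted p = 0.00559).

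**Figure D4:**
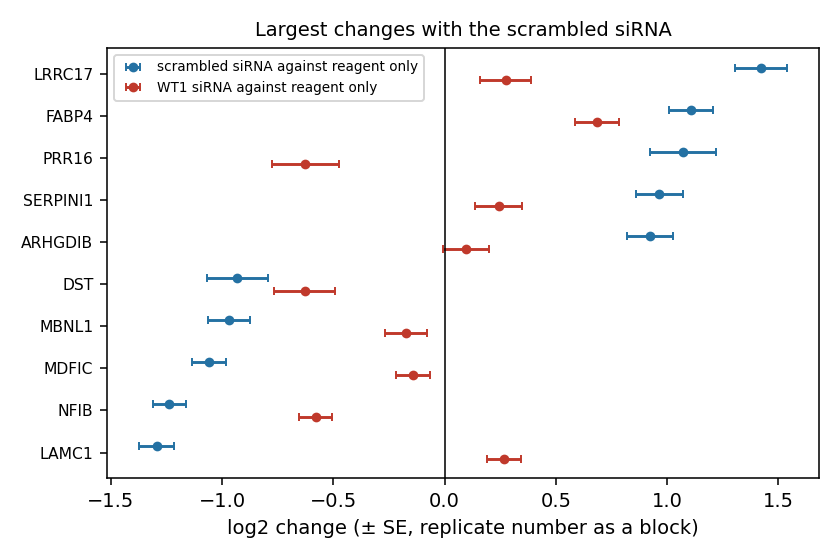
Log2 change against reagent (x axis) of the 10 genes named for scrambled siRNA against reagent (y axis), with scrambled siRNA and with WT1 siRNA, and bars of 1 SE from the blocked fit (n = 3 per group). LAMC1 changed by −1.29 with scrambled siRNA and differed by 0.27 with WT1 siRNA, and LRRC17 changed by 1.42 and differed by 0.27.

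Genes of G2/M and mitosis shifted down with the scrambled siRNA (median −0.10, 32 of 37 below 0; camera adjusted p = 3.34e-07 without the block, 1.36e-07 with it, and a blocked adjusted p of 0.557 with an estimated correlation). Genes of G1/S and DNA replication did so too (median −0.11, 30 of 32 below 0; adjusted p = 2.72e-06, 1.41e-07 and, with an estimated correlation, 0.557). In these lists limma called 0 genes over all genes, and adjusted over the list alone 1 and 4 fell, with PLK1 (−0.34) and CDC6 (−0.29) the smallest p-values. Extracellular matrix and mesenchymal genes shifted up (median 0.11, 30 of 41 above 0; adjusted p = 0.0488, 0.00172 and, with an estimated correlation, 0.557), with 8 higher and 4 lower genes, or 16 and 5 adjusted over the list alone. COL5A1 (0.68 at the probe set used for the list) and THBS2 (0.58) rose, and LAMC1 and COL1A2 (−0.55) fell. This shift was lost in the blocked fit without reagent replicate 1 (adjusted p = 0.111) or replicate number 1 (0.0961), and in the fit without the block in 5 of the 9 fits that left out an array, those without reagent replicates 1 and 3 (0.332 and 0.134), scrambled replicates 1 and 2 (0.169 and 0.301) and WT1 siRNA replicate 1 (0.0523). The G1/S call was lost there without reagent replicate 3 (0.0723). Oxidative phosphorylation genes passed only without the block (median 0.05; adjusted p = 0.0306, against 0.0524 with it and 0.695 with an estimated correlation), with 0 genes called. This call was lost without reagent replicates 1 and 2 (0.412 and 0.0777), scrambled replicates 1 and 3 (0.0766 and 0.224) and WT1 siRNA replicate 1 (0.0523).

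The astrocyte markers SLC1A3 (0.49) and CLU (0.32) rose with the scrambled siRNA, with 2 higher and 1 lower adjusted over the list alone. Of the adhesion receptors and CD97 ligands ITGA5 (0.49) and THY1 (0.39) rose and 0 fell, or 3 and 0 adjusted over the list alone with ADGRG1 (0.38). Of the 25, 19 lay above 0 (blocked camera adjusted p = 0.0524). LEF1 (−0.49) was the only call of the WT1 targets (2 higher and 2 lower adjusted over the list alone). The proneural list had 0 (0 and 2).

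At an unadjusted p under 0.05 limma gave 483 probe sets without the block and 2644 with it. The blocked count of 242 became 386 and 387 without WT1 siRNA replicates 1 and 3, 53, 20 and 117 without scrambled replicates 1, 2 and 3, 87, 22 and 116 without reagent replicates 1, 2 and 3, 77, 3 and 142 without replicate numbers 1, 2 and 3, and 535 with the groups of the comparison fitted alone.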

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

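The alternatives within the blocked fit, and leaving out a replicate number, were chosen after seeing the data. Arrays measure signal over a background that limits dim transcripts such as WT1, whose mean of 4.89 with its siRNA lies below every array median (6.45 or higher). With the replicate number as a block, WT1 passed (−0.74 against scrambled siRNA and −1.29 against reagent) and the counts became 726, 277, 242 and, against both controls, 143, since the block removes the spread between numbers from the error. The block left the numbers of shifted lists within 1.5 times. Without the block, leaving out single arrays gave WT1 changes of −0.85 to −0.61 and −1.43 to −1.08, and 1 to 3 probe sets against scrambled siRNA, 0 to 0 against reagent, 0 to 2 for scrambled siRNA against reagent and 0 to 0 against both controls. The 4 calls became 2 without WT1 siRNA replicate 1 or reagent replicate 3, 3 without scrambled replicate 3, and 1 without any other array. The 1 call of scrambled siRNA against reagent became 0 without scrambled replicate 1 or 2 or reagent replicate 2, and 2 without scrambled replicate 3 or reagent replicate 3. The shifted lists numbered 1 to 6 (4 with all arrays), 5 to 8 (7) and 2 to 7 (4). They fell to 1 without scrambled replicate 1 and 2 without WT1 siRNA replicate 2 in the first, and in the last became 2 without replicate 1 of any group or reagent replicate 3, and 7 without scrambled replicate 3. Quantile normalisation left 2 lists for scrambled siRNA against reagent, and fitting the groups of a comparison alone left 1 probe set against scrambled siRNA, for which the cause was not tested.

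In the blocked fit, leaving out an array or a replicate number gave WT1 changes of −0.83 to −0.67 and −1.39 to −1.18. WT1 no longer passed without replicate number 2 (−0.70, adjusted p = 0.0795, and −1.18, adjusted p = 0.0762), against an adjusted p of up to 0.0323 and 0.0166 under every other alternative to the blocked fit. The counts ran from 2 to 706 against scrambled siRNA, 0 to 465 against reagent, 3 to 387 for scrambled siRNA against reagent and 0 to 224 against both controls, each lowest without replicate number 2, where 3 of the 9 arrays are left out, and the cause beyond the fewer arrays was not tested. Shifted lists ran from 2 to 4 (3 with all arrays), 5 to 12 (10) and 2 to 9 (3). Against reagent they became 6 without replicate 2 of the WT1 siRNA or of reagent and 5 without replicate number 2. For scrambled siRNA against reagent they became 6 and 8 without reagent replicates 2 and 3, 7 without scrambled replicate 3, and 5 and 9 without replicate numbers 2 and 3. Of the named calls in the blocked fit, 29 against scrambled siRNA, 25 against reagent and 10 for scrambled siRNA against reagent, 2, 0 and 3 were kept without replicate number 2. Without reagent replicate 2 these were 23, 3 and 6, without WT1 siRNA replicate 2 they were 18, 8 and 10, and without scrambled replicate 2 they were 12, 18 and 7. Against reagent 11 of the 25 were kept without reagent replicate 1, 10 without replicate number 3 and 2 with the groups of the comparison fitted alone, and quantile normalisation kept all 29, 25 and 10.

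Fitting the groups of a comparison alone gave 390, 3, 535 and, against both, 2 probe sets in the blocked fit. An intensity trend with a robust prior gave 1091, 595, 485 and 284, and 8 lists for scrambled siRNA against reagent, and array weights gave 1140, 643, 782 and 309, and for all 3 settings the cause was not tested. An added 1.5-fold limit left 115, 50, 70 and 31, and an adjusted p under 0.1 gave 1312, 657, 518 and 325, both by construction. An estimated correlation left 0 lists in each comparison with or without the block (0, 0 and 0 in either). Called by fry, lists numbered 0, 0 and 0 without the block and 0, 1 and 0 with it, the 1 being hypoxia and glycolysis against reagent (adjusted p = 0.0225). Over all alternatives, the named genes kept their direction. This is no separate support, since most were picked for large changes or small p-values in these same arrays. In the blocked fit 941 values stayed on the same side of the threshold and 284 no longer passed. Without the block 488 stayed, 29 now passed and 32 no longer did.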

Other observations

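The test with the 28S control, the tests of cell cycle genes varying together between wells, the random lists for clock genes and the spread set beside the FOXO median were chosen after the result was seen, as were the lists of FOXO targets and clock genes. Among genes not yet described, values are from the blocked fit. Counts over all genes or adjusted over the list alone are given for some of the lists only. The p53 target FAS, a death receptor, fell against reagent (−0.58), the only call of 22 p53 targets there over all genes, with 4 lower adjusted over the list alone, while the list's median was 0.02, its mean −0.02 and camera pointed down (adjusted p = 0.489). TIGAR fell against scrambled siRNA (−0.41), and CCNG1 was lower with scrambled siRNA than with reagent (−0.37). Of 26 genes of NF-kB and inflammatory cytokines CXCL8, interleukin 8, rose against scrambled siRNA (0.58) and fell with scrambled siRNA against reagent (−0.71), and TNFAIP2 fell against scrambled siRNA (−0.32). In the lysosome and autophagy list LAMP2, a lysosomal membrane protein, fell with both siRNAs against reagent (−0.47 with the WT1 siRNA and −0.56 with the scrambled siRNA), and LIPA rose. Of the TGF-beta list LTBP3 rose against both controls (0.52 and 0.56), CCN2 rose against reagent (0.57), and TGFB2 (−0.45) and LTBP1 (−0.49) fell against scrambled siRNA. ITGA5, the fibronectin receptor chain, rose with both siRNAs against reagent (0.52 and 0.49), and ITGA7 fell (−0.48) while ITGB1 rose (0.38) against scrambled siRNA. PLAU, urokinase, rose with scrambled siRNA against reagent (0.57) with its receptor PLAUR (0.61) and TIMP2 (0.48), and fell with the WT1 siRNA against scrambled siRNA (−0.49). DKK3, of the Wnt list, rose with both siRNAs against reagent (0.49 and 0.34). None of these lists passed camera in these comparisons.

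Marker lists of other cell types were tested too. Of the epithelial markers DSP, desmoplakin, fell against both controls (−0.32 and −0.46) and KRT18 against scrambled siRNA (−0.44), 2 and 1 calls of 16 genes, or 4 and 2 adjusted over the list alone. The list's medians (0.02 and 0.04) lay above 0 and its means (−0.04 and −0.05) and camera pointed down, without passing (adjusted p = 0.96 and 0.466). GAD1 rose against scrambled siRNA (0.48), the only call of 15 neuron markers over all genes, and adjusted over the list alone it was also lower with scrambled siRNA than with reagent (−0.44). Among 9 oligodendrocyte markers, 18 leukocyte and microglia markers and 11 endothelial markers limma called 0 genes over all genes in any comparison, and adjusted over the list alone 1 endothelial gene, VWF (0.27), was higher with scrambled siRNA than with reagent. Of the 11 genes of the RNA interference machinery and of 17 heat shock genes 0 were called over all genes, and adjusted over the list alone the heat shock genes HSPB1 (−0.36) and DNAJB4 (−0.34) were lower with scrambled siRNA than with reagent. Of 23 mesenchymal glioma genes ANXA1 (0.57) and TNFRSF1A (0.26) rose and S100A4 (−0.30) fell against scrambled siRNA. Of 38 receptor tyrosine kinases and ligands FGFR1 (0.38) rose and PDGFC (−0.35) fell beside IGF1R. Of 33 apoptosis regulators BNIP3L and BNIP3 rose and DIABLO (−0.29) fell.

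Arrays with the same replicate number deviated from their group means together, as described with the processing. The 3' to 5' difference of the beta-actin control transcript had means of 0.07, 0.62 and 0.41 on the log2 scale in numbers 1, 2 and 3, that of GAPDH −0.01, 0.17 and 0.10, and that of 28S ribosomal RNA −3.28, −1.86 and 0.60. Some of the controls also differed between groups with the same sign in 3 of 3 numbers. The other pairs of a control and a comparison, all those of scrambled siRNA against reagent among them, did not. With 3 numbers the same sign throughout is common without any effect. The WT1 siRNA arrays lay below reagent in beta-actin (by 0.01, 0.06 and 0.24) and in the control HUMISGF3A (by 0.20, 0.18 and 0.10). They lay below scrambled siRNA in 28S (by 0.32, 0.23 and 0.59). In GAPDH they lay above reagent (0.02, 0.03 and 0.01) and scrambled siRNA (0.00, 0.02 and 0.01). Whether these shifts add to the calls was not tested. With the beta-actin and GAPDH differences as covariates in place of the block, limma made 0 calls against scrambled siRNA, where the block gave 726. These 2 differences moved together over the numbers. With the WT1 siRNA GAPDH was higher than with scrambled siRNA in 3 of 3 numbers and beta-actin lower in 2 of 3. As covariates they may therefore take up part of this comparison itself, so the count of 0 alone decides nothing about 3' bias. For scrambled siRNA against reagent, where neither difference had the same sign in 3 of 3 numbers, these covariates left 1 call. The block gave 242 there. This argues against 3' bias, as these 2 controls measure it, as the whole cause, but not as a part of it. With beta-actin and 28S limma made 610 calls, and with 28S alone 6, but 2 covariates that follow 3 numbers stand in for the block. RNA quality, with 3' bias as a part of it, therefore stays open, as does a day, passage or labelling batch, or a biological difference between cultures.

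In the blocked fit 121 probe sets set the scrambled siRNA arrays apart from both other groups, beside 143 for the WT1 siRNA and 31 for reagent. With the scrambled arrays shared between comparisons, the highest of 100 simulated overlaps was 90 (median 70, lowest 55, and 3.97 for independent lists). These are overlaps of lists of the same lengths taken by smallest p, not of calls. The correlation was −0.527 (−0.500 simulated) with a covariance of −0.00964 (−0.00307 simulated). The simulations drew each probe set independently, while real probe sets may vary together. The simulated range may thus be too narrow, so sharing the arrays is not excluded as the source. Over the 242 probe sets called in scrambled siRNA against reagent the WT1 siRNA differed by a median of 0.303 of the scrambled change (quartiles 0.0825 and 0.62), but this decides nothing about a response to any siRNA, since 121 of the 242 were picked for that difference and both changes use the reagent arrays. One odd scrambled array may contribute, with 34, 12 and 71 probe sets apart without scrambled replicates 1, 2 and 3, but leaving out reagent replicate 2 also left 17, so this stays open, as does an effect of the scrambled sequence itself, which was not tested. Among 100 splits within replicate numbers 2 reached 121, those by WT1 siRNA and by scrambled siRNA, and the highest below it was 50.

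Cell cycle lists were lower with both siRNAs than with reagent. Both comparisons use the same reagent arrays, so the 2 siRNA groups are not independent evidence. The mean of the G1/S genes was below 0 in 3 of 3 replicate numbers with the WT1 siRNA (−0.11, −0.29 and −0.16) and with the scrambled siRNA (−0.08, −0.16 and −0.14). The mean of the G2/M genes was below 0 in 3 of 3 numbers with the scrambled siRNA and in 2 of 3 with the WT1 siRNA (0.00, −0.12 and −0.16), so a response to any transfected siRNA, which would need all of them, could not be decided. Cell cycle genes varying together between wells may give the same shift, since with an estimated correlation it did not pass (adjusted p = 0.418 for G1/S with the WT1 siRNA), and the 2 explanations cannot be told apart with 3 wells per group.

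Several named genes that rose with the WT1 siRNA are known FOXO targets, such as CITED2, TXNIP and IGF1R, and higher FOXO activity may be a reason. The other 16 FOXO targets measured had a median change of 0.05 against scrambled siRNA and 0.0464 against reagent (standard error of the median 0.0693). Against scrambled siRNA the list passed camera at an unadjusted p under 0.05, though not with an estimated correlation. BCL6 (0.55) and BNIP3 (0.42, among the hypoxia genes that rose) were called there. Against reagent the list did not pass, with 0 called. Against each control 10 of the 16 lay above 0. A median below 0.05 against a control had been set beforehand to count against the hypothesis, and 0.0464 met this rule. The standard error of 0.0693 spans that limit. It was computed from the spread over the 16 genes, taken as independent, and does not measure the spread between cultures. The rule was met by less than this error, so the hypothesis stays open. BMAL1 and RORB both belong to the circadian clock, and a shift of the clock may be a reason for their rise. The other 12 core clock genes passed fry's mixed test, which counts both directions, at an unadjusted p under 0.05 against both controls. Their medians were 0.12 and 0.01, with 0 genes called. Of 1000 random lists of 12 genes 50.2% passed the mixed test against both controls too, so it does not set the clock genes apart. Camera passed at an unadjusted p under 0.05 against scrambled siRNA alone, there also with an estimated correlation (camera p = 0.047).

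Other splits of the same arrays were counted for each comparison. Without the block the WT1 siRNA against scrambled siRNA gave 4 probe sets in the real split and at most 0 in another, so that 1 of the 10 splits reached the real count. Against reagent 10 of 10 reached it (0, highest other 0), and for scrambled siRNA against reagent 1 of 10 did (1, highest other 0). In the blocked fit 1 of 4 splits reached the real count in each comparison (726, 277 and 242, highest other 0). All these splits are too few for a share under 5%. Against both controls without the block all 100 splits reached the real count of 0 and the highest other gave 2692. The 6 splits whose first group held the 3 arrays of one replicate number gave 184 to 2692, while the 64 with 2 arrays of one number and the 30 with 1 of each gave at most 1, which points to the structure by replicate number. In the blocked fit 1 of 100 splits within numbers reached 143, the real one, and the highest other, that by scrambled siRNA, gave 121. The real split thus gave the most calls of the 100. The blocked fit was chosen after its counts had been seen, so chance is not excluded by this share. The 31 probe sets that set the reagent group apart lay at the low end of the range simulated without group differences for lists of the same lengths (30 to 55, median 42, 1.5 for independent lists, correlation 0.371 against 0.499 and covariance 0.00622 against 0.00306).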
